A study of Mus musculus with 5 samples.

How the data were processed

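DNA methylation was measured by enhanced reduced representation bisulfite sequencing (ERRBS) in 5 libraries of mouse bone marrow LSK cells. LSK cells are Lin- Sca1+ cKit+ cells, the fraction that holds the blood stem cells and multipotent progenitors. Per the labels' protocols, genomic DNA was cut with MspI, an enzyme that cuts at CCGG, ligated to methylated adaptors, size-selected to fragments of 150 to 400 bp, bisulfite-converted, amplified and sequenced as single-end reads of 50 bp. Bisulfite turns unmethylated cytosine into a base read as T, and methylated cytosine is still read as C. The assay therefore covers CpG-rich fragments and leaves most of the CpG-poor genome unmeasured. A genomic change of C to T, or of G to A on the other strand, is read as loss of methylation.

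The libraries fall into 2 libraries whose titles read KO and 3 wild-type libraries, all on a C57BL/6 background. The genotype label of the 2 former libraries marks them as heterozygous (+/-), while their titles name a knockout. They are therefore called targeted here, without saying how many alleles were targeted. The targeted gene is not reported here. The series' design text names animals of 12 months for the transcriptome; no age is stated for these libraries. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The p-values of Fisher's exact test and of the pooled chi-square test hold no such spread.

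The authors' deposited tables list, per the file headers, each CpG cytosine by strand with its coverage and the percent of that coverage read as C and as T. Reads were aligned with Bismark to mm9 (NCBIM37), per the submitters' processing notes; the version is not given in the sources used here. The deposited coverage counts are whole numbers and were not normalized; the lowest coverage in every table is 10. The deposited percent values for C and T together never fall below 90.0, so positions with many other bases are missing from the tables. The percent of C times the coverage came within 0.01 of a whole number of reads for 99.97% of the entries of each library, and methylated and unmethylated read counts were recovered by rounding. The largest position on chromosome 1, 197193419, lies in the mm9 numbering, and all coordinates are given in mm9.

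The tables hold between 1354420 and 1473602 strand entries per library. Total coverage, summed over entries, was 122015958 and 151634492 in targeted libraries 1 and 2, and 140469056, 147303723 and 128994674 in wild-type libraries 1, 2 and 3. Median coverage per entry was 70 and 99 in the targeted libraries and 91, 96 and 75 in the wild-type libraries. Both strands of a CpG were merged, the highest 0.1% of coverage in each library was left out, and the analysis used the 1030056 autosomal CpGs covered in all 5 libraries. X-linked CpGs were kept apart, because the labels do not give the sex of the animals. Reads carried no molecular identifiers, so Wilson intervals and the limit set by a count of 0 (3 reads of the total) cover counting error only.

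Means per library were compared with exact permutation tests (two-sided) over the 10 splits of the 5 libraries, whose smallest possible p is 0.1. Tiles of 1000 bp with at least 3 CpGs, and single CpGs, were tested with the quasi-likelihood test of edgeR 4.0.16 on methylated and unmethylated read counts, with a factor for each library and a common dispersion. Tiles were called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 percentage points, and CpGs at an adjusted p under 0.05 and at least 25 points. Units with no methylated or no unmethylated read in any library were not tested, which left out 335 tiles and 272643 CpGs. Counts of a tile are summed over its CpGs, so a read that covers several CpGs counts once for each. Differences are the mean of the targeted libraries minus the mean of the wild-type libraries. Shares of called units were compared with Fisher's exact test (two-sided). It takes CpGs, tiles and positions as independent, although neighbours are linked and come from the same 5 libraries. Tables were handled with R 4.3.3 and the data.table package (1.17.8), and figures were drawn with matplotlib 3.10.9.

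Before the data were examined, the groups, tests, thresholds and most alternatives were set, and the part of chromosome 6 beyond 100 Mb, called distal chromosome 6, was set apart as a region that can hold DNA of another strain in targeted animals. The alternatives were a coverage minimum of 20, no upper limit on coverage, all chromosomes, no distal chromosome 6, each library left out, the replicate number as a block, limma 3.58.1 on log2 ratios with 1 read added to each count, a chi-square test of pooled reads, other tile sizes, CpG minimums and minimum differences, and other ways to average. A fit of tiles without their most different CpG and a robust edgeR fit were added after the data were seen. Tiles to be named were the called tiles outside distal chromosome 6 whose libraries do not overlap between groups, up to 10 in each direction.

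The tile and CpG tests were tested on simulated data with the coverage and wild-type levels of these libraries and 200 changed units. In a first simulation, with 1 overdispersion for all tiles, edgeR recovered 0% of the changed tiles at 10, 20 and 30 points and limma 0%, 2% and 1%, among 90703 tiles. The simulation was then changed so that the overdispersion followed the methylation level and varied between units, with 9 degrees of freedom taken from the fit to the measured tiles, which had been seen by then. With it, edgeR recovered 33% of tiles changed by 10 points, 78.5% of those changed by 20 points and 95% of those changed by 30 points, with 0, 5 and 7 false calls among 90703 tiles. limma recovered 6.5%, 15.5% and 46.5%. Over 1030056 CpGs, edgeR recovered 75.5%, 97% and 100% of CpGs changed by 30, 50 and 80 points, with 8, 12 and 12 false calls. Recovery and false calls were counted at an adjusted p under 0.05 alone, without the minimum difference required of a call. They therefore do not give the power of the calls made here. Power also depends on how the data were simulated. The limit on how close a level could come to fully unmethylated or fully methylated was changed along with the spread. Both simulations took the spread from the wild-type libraries only and gave it to the targeted libraries as well.

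The gene table at hand belongs to GRCm38, another assembly than that of the tables, and was not used. No gene was placed on mm9. Promoters, the 10 gene lists with 244 distinct genes, the named genes and the contexts of exon, intron and CpG island were therefore not analysed here.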

Results

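CpG methylation was compared between LSK cells from 2 targeted libraries and 3 wild-type libraries of C57BL/6 mice. The targeted libraries come from animals with a targeted gene, and the series asks whether this gene affects DNA methylation in blood stem and progenitor cells. Across the 1030056 autosomal CpGs covered in every library, the median coverage of a CpG was 88 and 113 reads in targeted libraries 1 and 2, and 105, 110 and 104 reads in wild-type libraries 1, 2 and 3. The mean chi-square per tile was 3.76 to 4.43 for pairs with targeted library 1 and 2.15 to 2.69 for all other pairs. A value of 1 would mark sampling noise alone only if every count came from a separate molecule. A read counts once for each CpG it covers in a tile, so these values cannot decide whether libraries agreed within sampling noise. The first principal component of tile methylation, 41.1% of the variance, set targeted library 1 apart (score -888, against 67.0 to 342.3 for the other 4).

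The first comparison asked whether the genome-wide level of CpG methylation differed. It was slightly higher in the targeted libraries, at 34.7% ± 0.501 (SD, n = 2) against 34.2% ± 0.0604 (SD, n = 3). Library by library, the mean level was 35.1% and 34.4% in the targeted libraries and 34.3%, 34.2% and 34.1% in the wild-type libraries. Both targeted libraries lay above all wild-type libraries, and the exact permutation test (two-sided) gave p = 0.1, the smallest p this design allows. Most of the difference of 0.551 percentage points came from targeted library 1: without it the difference was 0.196 points, and without targeted library 2 it was 0.905 points. Weighting CpGs by their reads moved the difference to 4.88 points, with pooled levels of 35.3% and 22.6% in the targeted libraries and 23.2%, 23.4% and 25.6% in the wild-type libraries, so that targeted library 2 lay below all wild-type libraries (exact permutation p = 0.6). This weighting mixes methylation with the spread of reads, which differed in targeted library 1. Its median coverage at CpGs under 20% was 1.07 times that at CpGs over 80%, against 1.64 to 2 times in the others.

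CpGs in LSK cells were mostly unmethylated or fully methylated, in both groups. The share of CpGs under 20% was 60.9% ± 0.396 (SD, n = 2) in the targeted and 61.3% ± 0.0227 (SD, n = 3) in the wild-type libraries. The share over 80% was 32.2% ± 0.619 against 31.6% ± 0.0606, and the share from 20 to 80% was 6.82% ± 0.223 against 7.08% ± 0.0514. Each of these 3 differences separated the groups completely, with an exact permutation p of 0.1. By density, CpGs in tiles with 1 to 2 covered CpGs were methylated at 83.6% against 82.4%, and those in tiles with 30 or more at 1.88% against 1.74%, again with an exact permutation p of 0.1 each.

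In percentage points, the shift of targeted library 1 was largest at partly methylated CpGs. At autosomal CpGs of 40 to 60% (mean of all libraries, 21136 CpGs) this library had 55.3%, targeted library 2 had 49.1%, and the wild-type mean was 48.6% ± 0.425 (SD, n = 3). At CpGs of 20 to 40% the levels were 35.6%, 28.9% and 28.1% ± 0.350, and at CpGs of 60 to 80% they were 75.8%, 70.9% and 70.1% ± 0.407. At CpGs under 20% they were 1.22%, 1.0% and 0.955% ± 0.0197, and at CpGs over 80% they were 94.7%, 94.1% and 93.8% ± 0.130. In log2 odds against the wild-type mean, targeted library 1 was higher in all 5 classes, by 0.36 under 20%, 0.50 at 20 to 40%, 0.39 at 40 to 60%, 0.42 at 60 to 80% and 0.25 over 80%. Both targeted libraries exceeded all wild-type libraries in each of the 5 classes (exact permutation p = 0.1 in each). Targeted library 1 also differed in coverage: its median coverage at CpGs under 20% was 1.07 times that at CpGs over 80%, against 2 times in targeted library 2 and 1.64 to 1.99 times in the wild-type libraries.

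**Figure D1:**
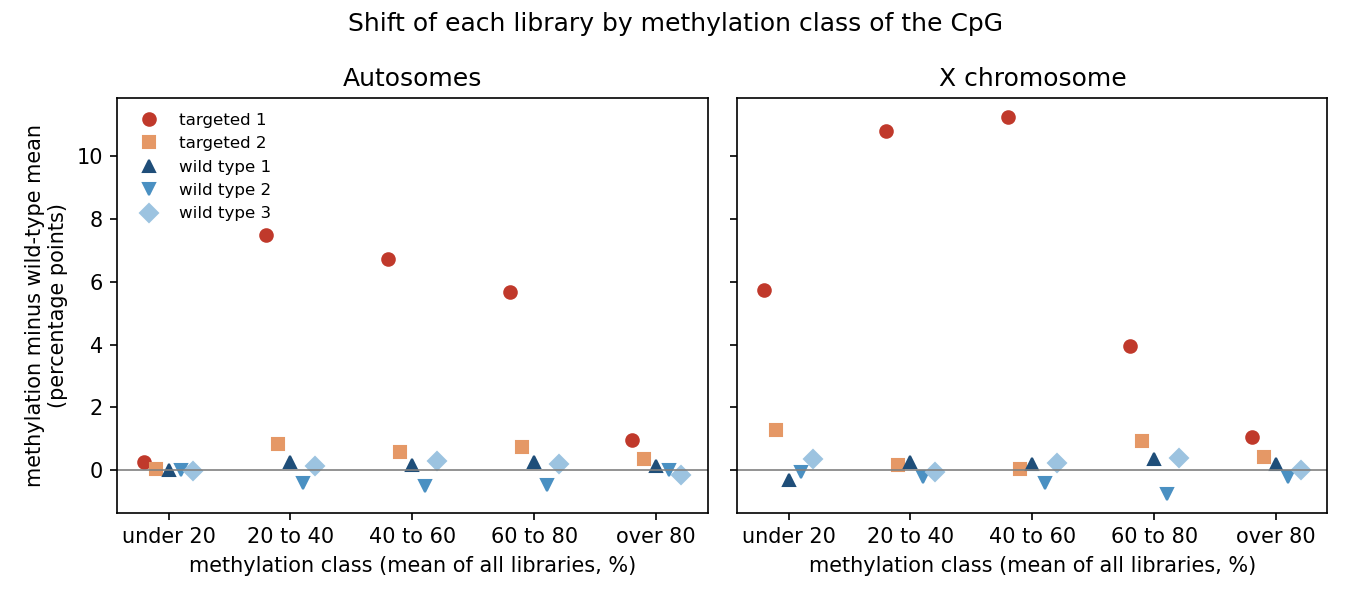
Methylation of each library minus the wild-type mean, in percentage points, for autosomal (left) and X-linked (right) CpGs grouped by their mean level over all 5 libraries; each point is 1 library. Targeted library 1 stands above all others in the classes between 20 and 80%, at 55.3% against a wild-type mean of 48.6% for autosomal CpGs of 40 to 60%.

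The second comparison asked which regions differed. In 1000 bp tiles, 2 of 90368 tested tiles were higher and 13 were lower in the targeted libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At single CpGs, 20 of 757413 were higher and 47 were lower. At each of these 67 CpGs the libraries of the groups did not overlap, which their selection by difference and adjusted p made likely in advance. Chromosome 6 beyond 100 Mb, here called distal chromosome 6, held 13 of the 15 tiles and 50 of the 67 CpGs. An unadjusted p under 0.05 was reached by 5711 tiles, 4828 of them higher and 883 lower in the targeted libraries. The other splits of the libraries, which mix the groups, gave 3042 to 4951 such tiles by the same test. Since targeted library 1 was higher in every autosomal methylation class, the direction of these tiles cannot be credited to the group. limma called 0 tiles (5857 with an unadjusted p under 0.05), and leaving out any library other tha targeted library 2 left between 1 and 4 lower tiles. Without the most different CpG of each tile, a fit chosen after the data were seen, edgeR called 2 higher and 0 lower tiles (2597 with an unadjusted p under 0.05).

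On chromosome 6 beyond 100 Mb, 42 CpGs were lower and 8 were higher in the targeted libraries. Of the tested CpGs 0.388% were called there, against 0.00228% on the rest of the autosomes (Fisher's exact test, odds ratio 170, 95% interval 97.0 to 315.3, p = 7.5e-74). For tiles the odds ratio was 349, with a 95% interval of 78.7 to 3337 (Fisher's exact test, p = 2.8e-21). Both tests take neighbouring units of the same libraries as independent, so their intervals are too narrow and their p-values too small. The 42 lower CpGs lay between 125125695 and 139493157. Neighbouring CpGs were mostly level: the 84 other CpGs within 50 bp of a lower CpG, 3 of them called, had a median difference of -0.0127 points, with quartiles of -2.89 and 2.56, and 4 were lower by over 10 points.

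The lower CpGs on distal chromosome 6 lay mostly near 0% in targeted library 1, and mostly near 0% or at intermediate levels in targeted library 2. Of the 35 lower CpGs over 80% in wild type, targeted library 1 was under 10% at 33. Targeted library 2 was under 10% at 16 and between 30 and 70% at 16. Among these 35, sites where both were under 10% ran from 125125695 to 133793442, with 1 more at 139493157. At the 15 of the 35 sites, from 134199720 to 139045639, where targeted library 1 was under 10% and targeted library 2 between 30 and 70%, the latter had a median of 47.2%, against a wild-type median of 92.8%.

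The CpG at 128871478 was at 0% in both targeted libraries (437 and 282 reads, which allow up to 0.686% and 1.06%), against 97.2% ± 1.92 (SD, n = 3; 48 to 81 reads), with an edgeR adjusted p of 5.8e-40. At 139045639 the levels were 0% and 51.2% (205 and 207 reads), against 91.4% ± 3.92 (124 to 230 reads; adjusted p = 5.9e-12), a call that ended with limma (adjusted p = 0.648, with alternatives other than the chi-square test from 4.5e-25 to 0.648). Among the 8 higher CpGs, that at 122513453 was at 95.8% ± 1.61 (SD, n = 2) against 50.6% ± 2.75 (121 to 264 reads; adjusted p = 1.0e-07), and that at 131737512 at 97.1% ± 2.32 against 39.6% ± 5.0 (66 to 136 reads; adjusted p = 5.4e-08). These 4 CpGs were chosen after their values were seen. The only higher tile of the region, 133503001 to 133504000, had 91.2% ± 0.219 against 60.5% ± 3.41 (edgeR adjusted p = 0.0115). Its call ended without targeted library 1 (adjusted p = 0.144), wild-type library 2 (0.0945) or wild-type library 3 (0.125) and with limma (0.664), and the alternatives other than the chi-square test ranged from 0.00444 to 0.664.

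Many positions of this region were missing from the targeted libraries. Of 23009 strand positions beyond 100 Mb with at least 50 reads in every wild-type library, 645 were absent from both targeted libraries, or 2.80%. Elsewhere on the autosomes 624 of 1286066 were absent, or 0.0485% (odds ratio 59.3, 95% interval 53.1 to 66.5, Fisher's exact test, which takes linked positions as independent). In the 5 windows of 1 Mb that end at 134 Mb between 31.4% and 56% of positions were absent from both. From 134 to 138 Mb at most 1.98% were absent from both, while 140, 73, 68 and 83 positions per window were absent from targeted library 1 alone and at most 2 from targeted library 2 alone. From 138 to 139 Mb 7.77% were absent from both and 36 positions from targeted library 1 alone, and from 139 to 140 Mb 40% were absent from both (32 of 80) and 0 from targeted library 1 alone.

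**Figure D2:**
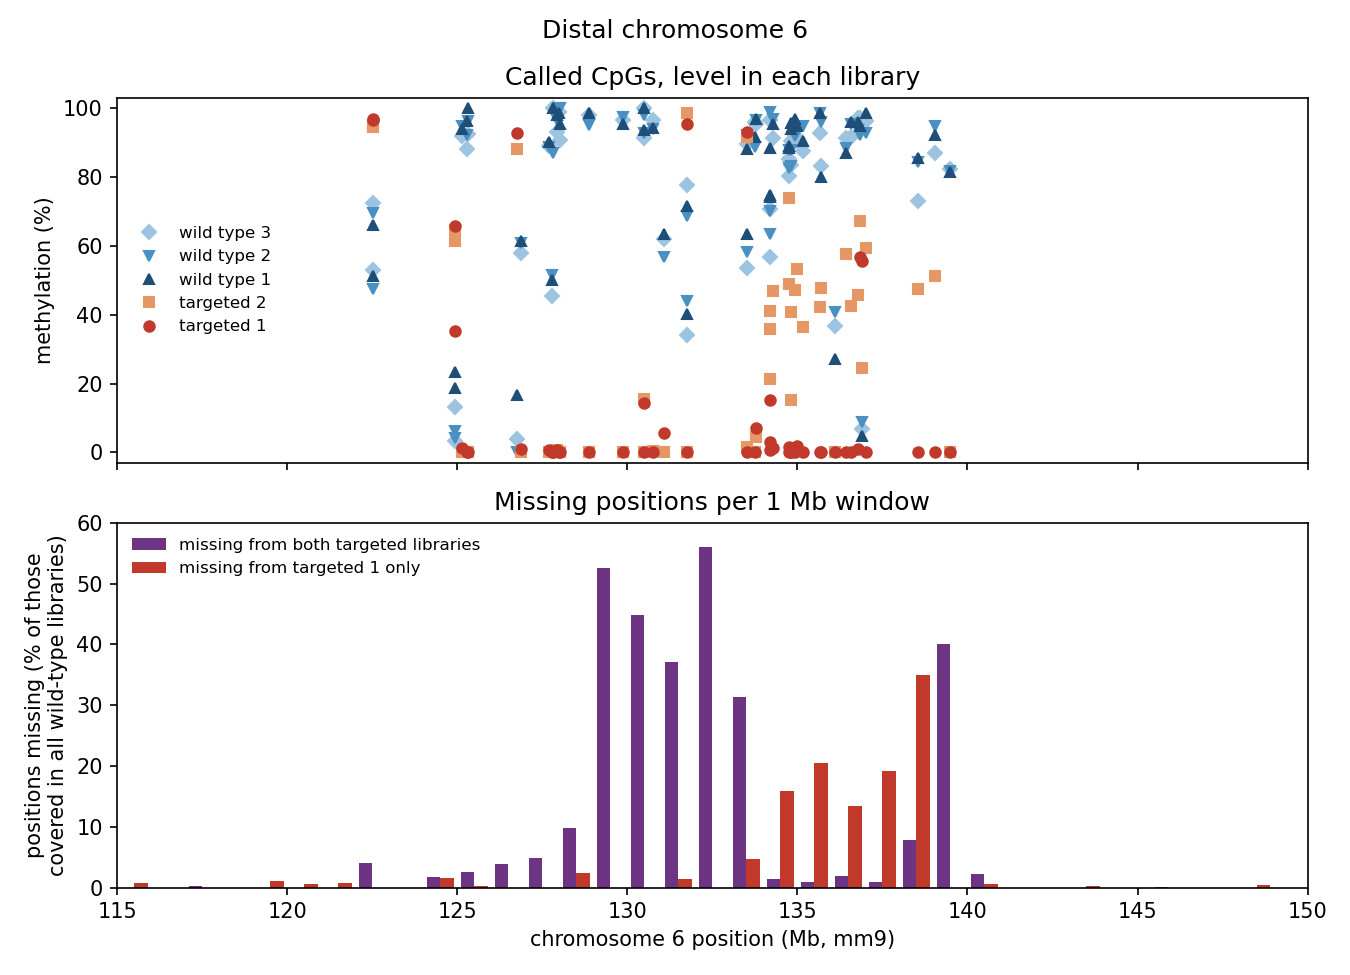
Top, methylation in percent of the called CpGs on distal chromosome 6 against their mm9 position, 1 point per CpG and library; bottom, the percent of positions with at least 50 reads in every wild-type library that are missing from both targeted libraries or from library 1 only, per 1 Mb window. Of the 35 lower CpGs over 80% in wild type, 15 up to 133793442 are under 10% in both targeted libraries, and targeted library 2 has a median of 47.2% at 15 from 134199720 on.

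Outside distal chromosome 6, a tile on chromosome 3 was more methylated in both targeted libraries. The tile from 105762001 to 105763000 held 28 CpGs. It was methylated at 14.6% ± 0.586 (SD, n = 2) against 0.0619% ± 0.0610 (SD, n = 3; edgeR adjusted p = 1.1e-04). Counts summed over its CpGs were 4091 to 5848 per library, and a read that covers several CpGs counts once for each. The rise lay in 9 CpGs from 105762536 to 105762610. Over these CpGs 28.2% and 27.8% of counts were methylated in the targeted libraries. In wild-type libraries 1, 2 and 3 the share was 0.0481%, 0.0946% and 0%. Over the other 19 CpGs of the tile at most 0.222% of counts were methylated in any library. Coverage of the 9 CpGs relative to these 19 was 1.02 and 1.16 in the targeted libraries and 0.787, 0.755 and 0.568 in the wild-type libraries. The call was kept with each library left out (highest adjusted p 0.00189) and ended with limma (adjusted p = 0.648), where alternatives other than the chi-square test ranged from 1.1e-06 to 0.648.

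**Figure D3:**
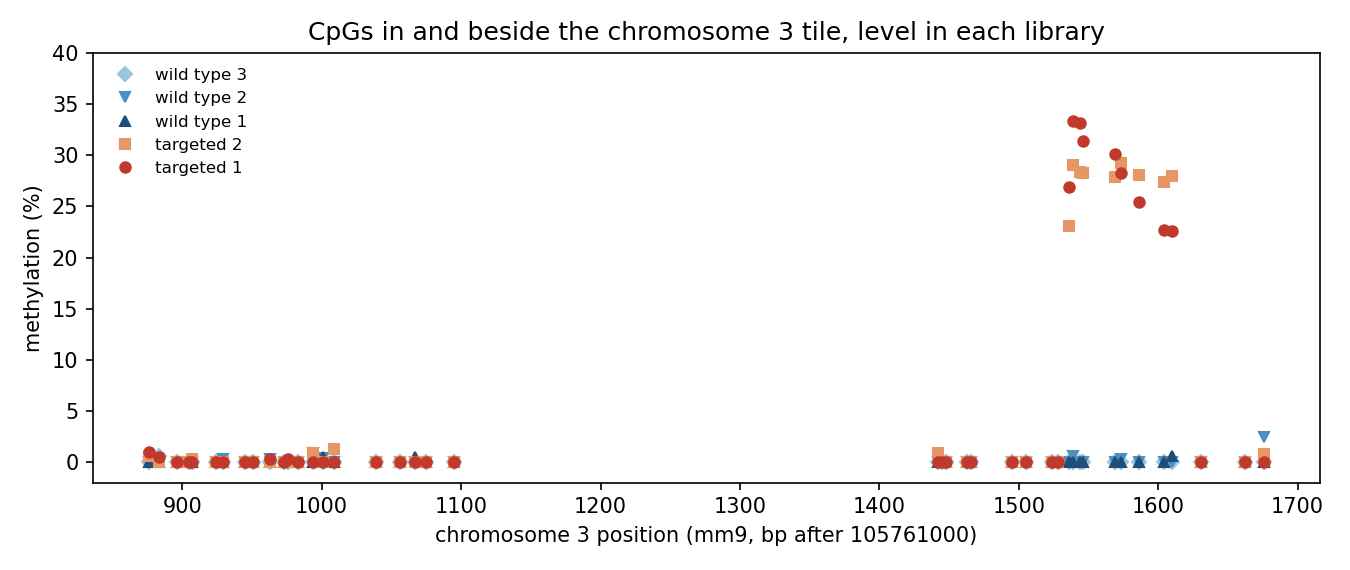
Methylation in percent of each CpG in and beside the called tile on chromosome 3 against its mm9 position, 1 point per CpG and library. In the 9 CpGs from 105762536 to 105762610 both targeted libraries lie between 22.6% and 33.3%, and all wild-type libraries at or under 0.585%.

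A tile on chromosome 9, 42862001 to 42863000, held 4 CpGs, with counts summed over them of 293 to 524 per library. It was methylated at 78.5% ± 2.33 (SD, n = 2) against 96.3% ± 1.62 (SD, n = 3; edgeR adjusted p = 0.0254). Its CpG at 42862993 was at 58.6% and 53.4%, against 96.6%, 98.0% and 86.3%. The tile's call ended with any library left out (edgeR adjusted p from 0.0677 to 0.236 for the wild-type libraries). It also ended without its most different CpG (difference -2.74 points), with limma and without distal chromosome 6. Across the alternatives other than the chi-square test the adjusted p ranged from 0.00146 to 1.0.

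At a smaller difference than the minimum of 10 points, and chosen after their values were seen, 2 further tiles passed the adjusted p. On chromosome 8, 74093001 to 74094000 (21 CpGs) was at 4.79% ± 1.41 (SD, n = 2) against 0.227% ± 0.113 (SD, n = 3; adjusted p = 0.00563). It no longer passed without wild-type library 2 or with limma. On chromosome 11, 117829001 to 117830000 (41 CpGs) was at 0.561% ± 0.0186 against 3.13% ± 0.557 (adjusted p = 0.0417). This tile no longer passed with any library left out, without distal chromosome 6 or with limma. It also failed at a coverage minimum of 20, with at least 5 CpGs per tile and without its most different CpG.

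The third measurement was of the sex chromosomes, since the labels do not give the sex. Of X-linked entries 47.8% lay between 20 and 80% in targeted library 1, 40.8% in targeted library 2 and 40.1% to 40.5% in the wild-type libraries, against 6.09% to 6.63% on autosomes. Between 3 and 8 entries lay on the Y chromosome in each library. The high X-linked share and the few Y entries in every library argue against a difference in sex between the groups. Median X coverage over median autosomal coverage was 0.971 in targeted library 1 and 0.818 to 0.840 in the other 4. With all chromosomes in the fit, edgeR called 0 of 2469 X-linked tiles (193 with an unadjusted p under 0.05) and 1 of 24766 X-linked CpGs.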

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

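In this part the comparison of missing positions, the count of other splits and the comparison by CpG density were set before their results were seen, the latter after recovery by the same factor everywhere had been tested; the other tests of explanations were chosen after the result was seen.

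The lower CpGs on distal chromosome 6 go with a signal outside the methylation values, the 645 positions missing from both targeted libraries there. Their frequency was 57.8 times that on the rest of the autosomes, which is what sequence variants of another strain would give. Loss of methylation over wider stretches would lower the neighbours as well, and the other CpGs within 50 bp that are over 80% in wild type, called or not, had a median difference of -0.0783 points (74 CpGs, 2 of them called). A single chromosome with such DNA in each targeted animal, which would leave these CpGs near the middle, goes against library 1, under 10% at 94.3% of the 35 lower CpGs that are over 80% in wild type, and against library 2 in the 5 Mb before 130 Mb, under 10% at 100% of 10 such CpGs. Over the whole region library 2 was under 10% at 45.7% of the 35 CpGs, and positions missing from both libraries were frequent again from 139 to 140 Mb, at 40%, which goes against a single change along the chromosome. These values may therefore reflect base changes read as unmethylated cytosine rather than methylation, with 2 copies in library 1 and, in library 2, 2 copies before 134 Mb, 1 copy from there to 139045639 and 2 again beyond it, as a hypothesis found on the same data; how many alleles were targeted was not tested.

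The X-linked level of targeted library 1, 60.1% over 24937 CpGs outside the autosomal comparison, stands above the 54.1% to 54.5% of the wild-type libraries and the 54.8% of targeted library 2, and goes with its rise at partly methylated autosomal CpGs; incomplete bisulfite conversion would raise unmethylated CpGs most, and on autosomes the rise under 20% was 0.0398 times the rise at 40 to 60%, while on the X chromosome it was 5.74 points, or 0.511 times, which conversion, acting on all DNA of a library, would not give with an autosomal rise 0.0466 times as large. A genotype effect shared by both targeted libraries is argued against as the whole cause by library 2, whose rise at autosomal CpGs of 40 to 60% was 0.0852 times that of library 1. On the X chromosome library 2 lay within the wild-type range at 20 to 40% (27.6% against 27.2% to 27.7%) and at 40 to 60% (43.6% against 43.2% to 43.8%). It exceeded all wild-type libraries in the other X-linked classes and in each of the 5 autosomal classes. Over 80% on autosomes it had 94.1% against 94.7% in library 1 and a wild-type mean of 93.8%, so a smaller shared part stays open. Recovery of methylated molecules by the same factor everywhere would shift the log2 odds alike, but the shifts of library 1 differed between the X chromosome and autosomes. They were larger on the X under 20% (0.71 against 0.36), at 20 to 40% (0.71 against 0.50) and, by 0.26, at 40 to 60% (0.65 against 0.39). They were smaller at 60 to 80% (0.29 against 0.42) and alike over 80% (0.25 on both). A recovery that grows with CpG density may account for part of the autosomal shift, since the log2 odds shift at CpGs of 40 to 60% was larger by 0.22 in tiles with 30 or more covered CpGs (0.56) than in tiles with 1 to 2 (0.34), only just past the difference of 0.2 set beforehand. At 40 to 60% the X-linked shift was 0.83 with 30 or more covered CpGs, larger by 0.27 than on autosomes, and 0.75 against 0.47 with 10 to 29. With 3 to 9 it was 0.48 against 0.36 and with 1 to 2 it was 0.41 against 0.34. The classes were set by the mean of all 5 libraries, library 1 included. With 30 or more covered CpGs the wild-type mean of this class was 41.3% on the X and 46.5% on autosomes. Comparing the X with autosomes therefore cannot decide whether recovery, by 1 factor or by density, gave the larger X-linked shift. A difference of this animal or its cells stays open as untested.

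The tile on chromosome 3, chosen because it was called, kept a difference of 13.8 points without its most different CpG, a fit that left 0 lower tiles, which argues against a sequence variant at a single CpG, and it was 1 of 2 tiles still called without library 1 (adjusted p = 0.00162 by edgeR), which argues against the recovery bias of that library as the cause. The coverage of its 9 raised CpGs relative to the other 19 of the tile was 1.02 and 1.16 in the targeted libraries and 0.787, 0.755 and 0.568 in the wild-type libraries, 1.55 times as high on average. For unmethylated counts alone these ratios were 0.731 and 0.839 against 0.786, 0.754 and 0.568. Reads of a further, methylated copy of this sequence in the targeted animals may thus have aligned here, a hypothesis formed from these values; a gain of methylation at the locus that raised its recovery stays open. The 15 called tiles compare with 0 in the highest of the other splits of the 5 libraries, and 1 of the 10 splits, the real one, gave as many, too few splits for a share under 0.05.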

How the results depend on the processing

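The fit without the most different CpG of each tile and the robust fit were chosen after the data were seen; the other alternatives were set before. The mean methylation difference was positive under each alternative, from 0.196 to 0.905 points with a library left out, 4.88 by pooled reads, 1.12 over all CpGs of each library, and 0.528 to 0.611 under the others. The pooled value also depends on where the reads of each library fell, so it is not a measure of methylation alone. By pooled reads and over all CpGs the groups overlapped (exact permutation p = 0.6 and 0.4), with targeted library 2 at 22.6% against 23.2% to 25.6% and at 35.3% against 34.6% to 36.5%. Higher and lower tiles, 2 and 13, became 1 and 3 with at least 5 CpGs, 0 and 0 with limma, 814 and 76 with the pooled chi-square test, which ignores the spread between libraries, 1 and 0 without distal chromosome 6, and 1 and 6 at 25 points; leaving out a library gave 1 to 8 higher and 1 to 10 lower tiles. Without their most different CpG 2 higher and 0 lower tiles were called, and 5 tiles of chromosome 6 turned to differences of 0.195 (128871001), 2.33 (133752001), 0.640 (129880001), 0.251 (133516001) and 1.05 (127995001) points, since 1 CpG carried each. The robust fit also called 2 and 13. Higher and lower CpGs, 20 and 47, became 12 and 25 with limma, 321 and 73 with the chi-square test, 10 and 5 without distal chromosome 6, and 12 to 39 and 38 to 48 with a library left out. Unless named, the cause was not tested. Other alternatives stayed within 1.5 times. The replicate numbers are shared by 2 pairs only, whose deviations correlate at 5.1e-04 and 0.0668, so they do not pair the libraries; with the replicate number as a block, 4 tiles were higher and 19 lower, and 15 and 45 CpGs. Alternatives for promoters were not run. With a targeted library left out, the other is assumed to vary like the wild type. In simulated data, at an adjusted p under 0.05 without a minimum difference, edgeR recovered 0% of tiles changed by 10 points with 1 overdispersion for all tiles. It recovered 33% with the spread changed after the fit was seen. The limit on extreme levels was changed too, so this gap cannot be credited to the spread alone. What this depth can show depends on the simulation assumed.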

Other observations

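All values in this part were chosen after they were seen. Outside distal chromosome 6 and the chromosome 3 cluster, 8 further CpGs were called by edgeR, 1 of them in the chromosome 9 tile. On chromosome 6, 58116433 was at 31.1% and 23.7% in targeted libraries 1 and 2 against 92.9%, 100% and 100% in the wild-type libraries (adjusted p = 1.6e-05), with 132 and 76 reads against 14, 10 and 22. On chromosome 17, 90274179 was at 41.0% and 22.2% against 85.2%, 97.1% and 96.4% (adjusted p = 1.2e-06), with 83 and 108 reads against 27, 34 and 56, so both sites also had more reads in the targeted libraries. On chromosome 17, 45802051 was higher, at 37.4% and 26.4% against 1.10% to 2.83% (adjusted p = 3.97e-04). On chromosome 6, 59983384 was at 61.7% in both targeted libraries against 95.5% to 97.3% (adjusted p = 4.99e-04), and on chromosome 1, 102890930 was at 66.0% and 55.0% against 93.8% to 94.6% (adjusted p = 0.00347). Of these 5, the call at 90274179 ended under 1 of the 11 alternatives other than the chi-square test, but held with each wild-type library left out. Those at 58116433 (highest adjusted p 0.111, without wild-type library 3), 59983384 (0.351, without wild-type library 2), 45802051 (0.183, without wild-type library 1) and 102890930 (0.628, without wild-type library 2) did not. The calls at 24191982 on chromosome 11 and 127701513 on chromosome 2 rested on wild-type libraries that differed among themselves, from 55.0% to 89.8% and from 35.0% to 89.7%.

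Single libraries also stood apart at neighbouring CpGs. Targeted library 2 was between 32.4% and 39.1% at 6 CpGs from 25636949 to 25636994 on chromosome 18, where the other 4 libraries lay between 63.6% and 90.9%. Wild-type library 2 was more than 30 points below all others at 5 CpGs between 35 and 40 Mb on chromosome 17. CpGs at which a single library stood apart numbered 33 and 42 in targeted libraries 1 and 2. In wild-type libraries 1, 2 and 3 they numbered 78, 81 and 32. For targeted library 1, 12 of them lay between 135 and 140 Mb of chromosome 6 and 8 between 130 and 135 Mb. In the direction opposite to the missing positions, 374 of 23047 strand positions beyond 100 Mb of chromosome 6 with at least 50 reads in both targeted libraries were absent from all wild-type libraries, against 804 of 1323089 elsewhere.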
